A study of Mus musculus with 16 samples.

How the data were processed

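Lungs of mice 8 to 10 weeks old were digested with collagenase IV, papain and DNase, red cells were lysed, dead cells were removed, and single cells were sequenced as 10x Genomics 3′ libraries on a NovaSeq X Plus, per the labels. The protocol names a v2 or v3 chemistry without saying which was used for which library. The deposited values are UMI counts, made by the authors with Cell Ranger 7.1.0 according to the submitters' processing notes, as 1 count matrix per lung library with no normalization. Those notes name the build GRCh38, a human build, although all 32285 feature IDs were mouse Ensembl IDs, and no positions were computed. The matrices of PBS, model, Maf and BLM_Maf (6 libraries) held all barcodes, and those of the Apbb2 and Tns3 titles (4 libraries) held only barcodes with 500 or more UMIs. The remaining 6 samples, spleen T cell receptor libraries with the titles TCR_NC and TCR_VC, came without processed count tables and were not analysed.

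Cells in the 6 unfiltered matrices were barcodes above an order-of-magnitude level set from the top 3000 barcodes, plus barcodes of at least 500 UMIs that differed from the pooled profile of barcodes with 100 or fewer UMIs at an adjusted p of 0.001 or less. In all 10 libraries, cells had at least 500 UMIs and 300 genes, and at most 20% mitochondrial UMIs. The cells with the highest scores against simulated doublets were then left out, as many as 0.8% per 1000 cells of the library. This left 120853 of 136548 cells. That quota left out unequal shares of the classes: 63.7% of alveolar type 2 cells, 23.6% of fibroblasts and 2.41% of T cells. Counts were scaled and log-transformed, 2000 variable genes (without Maf, Apbb2, Tns3 and the mitochondrial, ribosomal and haemoglobin genes) were reduced to 40 principal components, and a graph of 20 neighbours was clustered with the Leiden method at a resolution of 1.5, with no integration across libraries. The 67 clusters were named from fixed marker lists, which gave 19 classes. A class name stands for cells with that marker profile, and a cluster with at least 75% doublets was left unnamed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and igraph 0.11.9 did these steps.

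Counts were summed over the cells of a class in each library, for classes with at least 30 cells in every library of a comparison. Fits used edgeR 4.0.16 in R 4.3.3 with limma 3.58.1, with TMM normalization, the filterByExpr filter and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 over the genes of each class. The 4 libraries with BLM in the title were compared with the 4 of the same targets without it, with the target as a covariate (4 residual degrees of freedom). BLM_Maf was compared with Maf in a fit of those 4 libraries. BLM_Maf against model, Maf against PBS, and the difference between the BLM_Maf-to-Maf change and the model-to-PBS change came from a fit of all 10 libraries by group (2 residual degrees of freedom), in which PBS and model, 1 library each, are assumed to vary like the replicated groups. The labels do not say whether the 2 libraries of a group came from separate mice, so p-values measure the spread between these samples. The remaining pairs of single libraries have no test: their values are ratios of CPM (UMIs of a gene scaled to a common class total) with exact 95% intervals that cover counting error only. A count of 0 was taken to allow up to 3 counts.

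The 21 gene lists, the markers, the comparisons and the rule for named genes were fixed before the data were examined. List tests were planned for the 3 comparisons against Maf, model or titles without BLM. Those for Maf against PBS, and the random lists for single-library pairs, were not part of that plan. List tests were limma's fry, with Benjamini-Hochberg adjustment over the class and list pairs of a comparison; single members were also adjusted over the list alone. In single-library pairs, a list's median log2 ratio of CPM + 1 was set against 10000 random lists matched on mean expression. Class shares were compared between 4 and 4 libraries with an exact two-sided permutation test over 70 arrangements that ignore target and library set, adjusted over 19 classes, and shares of single libraries carry exact Clopper-Pearson intervals. The named genes were, in the 3 comparisons against Maf, model or titles without BLM, up to 3 highest and 3 lowest log2 fold changes among calls with an average log2 CPM of 5 or more, in the 5 classes with most calls. Across the BLM titles, the mean difference of such a gene also had the same sign in all 3 targets. In the comparisons against Maf or model, all libraries of 1 group lay on one side. For Maf against PBS and the difference of differences the named genes were the 3 calls with the smallest p. For lists they were the 2 to 4 members with the smallest p. For single-library pairs they were taken from the 3 highest and 3 lowest ratios in macrophages and fibroblasts with at least 50 CPM in 1 library and 20 counts in both. Maf, Apbb2 and Tns3 were always given. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, sex-linked and unnamed predicted genes were not named.

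The fits were tested on simulated data with 200 changed genes. In the 4-against-4 fit, 58% of genes with a simulated fold of 2 and 95% with a fold of 4 were recovered in T cells. For the difference of differences these values were 0% and 26%, so that comparison could find only large changes. The simulated counts used edgeR's fitted dispersions, which are already drawn together over genes. Real genes may differ more in spread, so recovery in the real data may be lower than these values. Alternatives were DESeq2's size factors, the DESeq2 1.42.0 Wald test, no expression filter, a minimum of 1000 UMIs, a mitochondrial limit of 10%, doublets kept, classes called per cell, other covariates and blocks, fits of fewer libraries, and each replicated library left out in turn.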

Results

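Single-cell RNA was measured in 10 mouse lung libraries of 8 groups, in a series on immunopeptidome profiling in pulmonary fibrosis. PBS and model had 1 library each, BLM_Maf and Maf had 2 each, and BLM_Apbb2, Apbb2, BLM_Tns3 and Tns3 had 1 each. The titles name Maf, Apbb2 and Tns3 (genes ENSMUSG00000055435, ENSMUSG00000029207 and ENSMUSG00000020422), and the series text names a Maf-peptide vaccine. The labels do not spell out BLM, do not say that model is BLM, and do not say what animals of the titles without BLM received. Total UMIs were 85687346 in PBS, 109927572 in model, 51521090 and 90572211 in BLM_Maf 1 and 2, and 86995437 and 93444231 in Maf 1 and 2. They were 108165315 in BLM_Apbb2, 88908083 in Apbb2, 104677947 in BLM_Tns3 and 68417541 in Tns3. Between 7486 cells (BLM_Maf 1) and 17312 cells (Maf 1) were kept per library. Median UMIs per cell, taken before doublets were left out, ran from 2676 in Maf 1 to 4698 in model.

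The libraries fell into 2 sets that followed the targets. Gm42418, a locus known to overlap ribosomal RNA and chosen after its values were seen, stood at 26237 to 40256 CPM in the PBS, model, Maf and BLM_Maf libraries and at 410 to 580 CPM in the Apbb2 and Tns3 titles. Lars2, chosen likewise, stood at 889 to 1906 CPM and at 28.0 to 32.9 CPM. Comparisons across the sets therefore cannot be told apart from a difference in library making, whereas pairs within a set do not contrast the sets.

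The cells recovered were rich in lymphocytes, and cell class shares differed widely between single libraries. Shares are of cells kept after digestion, dead-cell removal and the doublet quota, not of lung tissue. Recovery may have differed between libraries: endothelial cells numbered 156 in BLM_Maf 1 and 3 in BLM_Maf 2. T cells made up 29.8% (95% interval 29.0 to 30.7) of PBS cells and 47.4% (46.5 to 48.3) of model cells. Interstitial macrophages made up 0.756% (0.605 to 0.933) of PBS cells and 5.25% (4.86 to 5.66) of model cells, fibroblasts 18.8% (18.0 to 19.5) and 6.77% (6.33 to 7.23), and NK cells 16.5% (15.8 to 17.2) and 6.02% (5.60 to 6.46). B cells made up 15.8% ± 3.12 (SD, n = 4) of the 4 libraries with BLM in the title and 11.1% ± 1.93 (SD, n = 4) of the 4 without, and were higher with BLM in all 3 targets. This difference had an exact two-sided permutation p of 0.0286, the smallest that 70 arrangements allow. Over 19 classes that p adjusts to 0.543 when 1 class alone reaches it, so a single class could not pass whatever its values.

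That test, the only one run on shares, permutes across targets and library sets, and B cells were the 1 class with an unadjusted p under 0.05. Monocytes were higher with BLM in all 3 targets too, at 2.20% and 1.36% in BLM_Maf against 0.710% and 0.622% in Maf, 4.22% against 3.74% for Apbb2 and 4.06% against 2.51% for Tns3. Their means were 2.96% ± 1.41 and 1.90% ± 1.51 (SD, n = 4 each, exact permutation p = 0.286). Fibroblast shares were 3.76% ± 4.36 (SD, n = 4) with BLM and 7.69% ± 7.97 (SD, n = 4) without (exact permutation p = 0.4). They were lower with BLM in all 3 targets, at 5.49% and 9.14% in BLM_Maf against 18.0% and 9.85% in Maf. For Apbb2 they were 0.109% against 0.623%, and for Tns3 0.316% against 2.28%. Alveolar macrophage shares were 10.8% ± 3.96 and 11.0% ± 9.07 (SD, n = 4 each, exact permutation p = 0.943), and their difference of -0.220 points became 1.13 points without BLM_Maf 1, 0.697 without BLM_Maf 2, 2.38 without Apbb2 and 2.42 without Tns3. Interstitial macrophage shares were 6.30% ± 1.25 and 5.47% ± 4.10 (SD, n = 4 each, exact permutation p = 0.8), and their difference of 0.827 points became -0.287 points without Maf 1 and -0.0820 points without Maf 2.

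**Figure D1:**
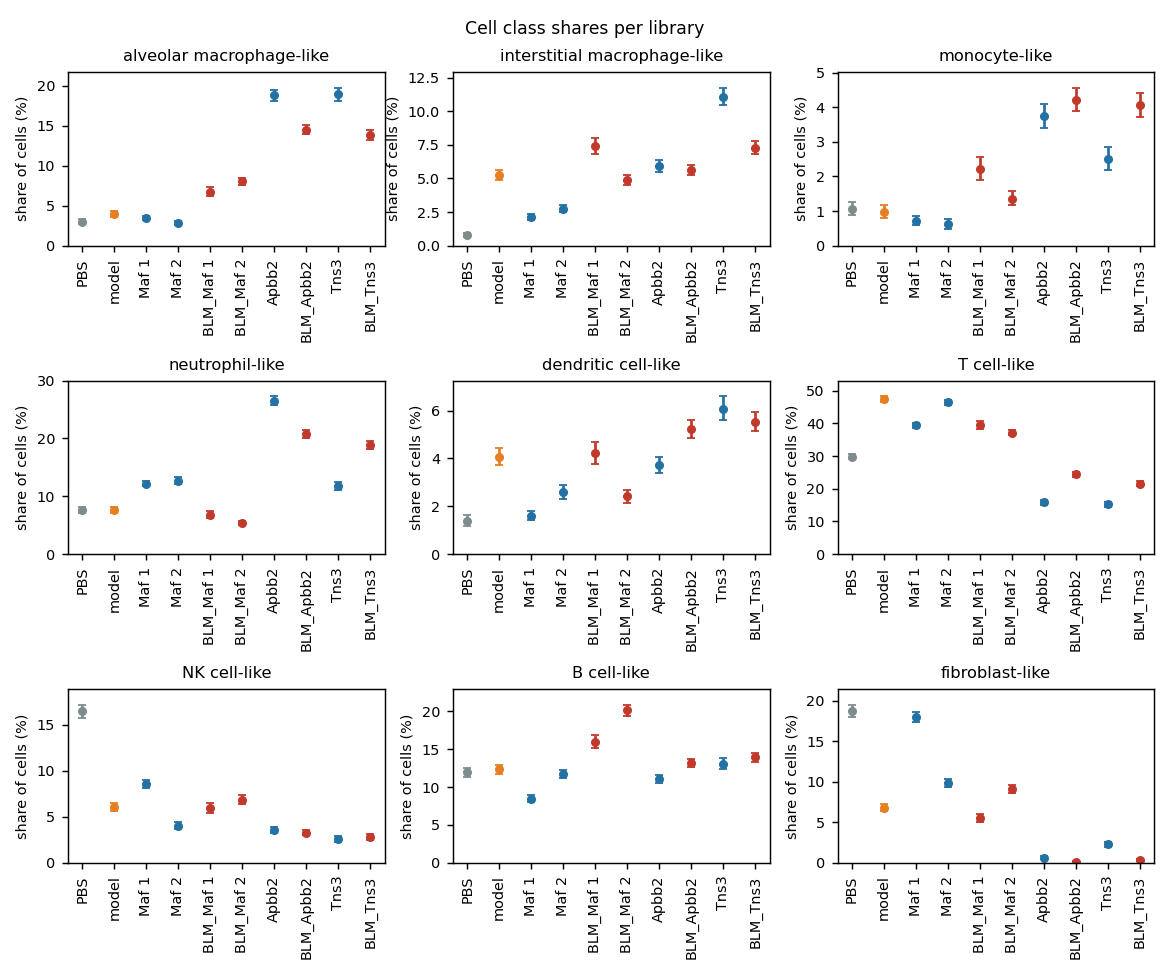
Share of cells (%, vertical axis from 0) of 9 cell classes in each of the 10 libraries, with points for single libraries (grey PBS, orange model, red titles with BLM, blue titles without) and bars for exact 95% binomial intervals. Interstitial macrophages were at 0.756% in PBS and 5.25% in model, and fibroblasts at 18.8% and 6.77%.

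The comparison of the 4 BLM-titled libraries with their 4 counterparts asked what BLM changed across the targets. In neutrophils, Olfm4, a granule glycoprotein of a neutrophil subset, fell with BLM (log2 fold change -1.70, SE 0.232, adjusted p = 0.0177, n = 4 and 4). Its level was 10.7 and 23.2 CPM in BLM_Maf against 69.7 and 52.6 in Maf, 18.8 CPM in BLM_Apbb2 against 39.4 in Apbb2, and 16.5 CPM in BLM_Tns3 against 55.1 in Tns3. Cluster 29, led by the granule genes Ngp, Camp and Ltf, held 0.980% and 8.43% of neutrophils in BLM_Maf against 13.1% and 4.91% in Maf, 1.56% against 4.22% for Apbb2 and 1.33% against 4.40% for Tns3, and no test set Olfm4 apart from this shift. Ccl7, a monocyte-attracting chemokine named after its values were seen, fell in neutrophils too (log2 fold change -2.48, SE 0.382, adjusted p = 0.0381). The other 7 classes had no call.

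Those were the 2 calls among 92195 class and gene pairs by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 7856 pairs at an unadjusted p under 0.05 and 181 calls by DESeq2. The count was 15 without Tns3, 8 without Maf 1, BLM_Apbb2 or BLM_Tns3, 7 without Apbb2, 5 without Maf 2 and 3 without either BLM_Maf library, and 10 with the replicates as a block in place of the target. The Olfm4 call was lost without BLM_Tns3 (adjusted p = 0.0719), without Tns3 (0.0805), with model and PBS added (0.0886), with doublets kept (0.238) and without the target covariate (0.345).

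Cytokine transcripts had mostly lower values with BLM in macrophages in the fit that pools the 3 targets. That fit gives 1 value over the targets and does not show the direction within each. In alveolar macrophages, 23 of 25 inflammatory cytokines and chemokines had a log2 fold change below 0 (median -0.34), and 8 were lower when adjusted over the list alone, with Ccl7 at -1.25, Ccl3 at -0.88, Tnf at -0.91 and Il1a at -0.63. Over all genes tested, 0 of them passed. Of alveolar macrophages, cluster 17 held 12.3% and 24.3% in BLM_Maf against 43.0% and 20.9% in Maf. It held 3.94% against 50.0% for Apbb2 and 11.7% against 16.4% for Tns3. Cluster 9, with the cytokine genes Il1a and Osm among its leading genes, held 44.4% and 34.6% in BLM_Maf against 32.4% and 36.1% in Maf. That cluster held 56.3% against 36.7% for Apbb2 and 47.5% against 47.3% for Tns3. In interstitial macrophages 21 of 25 cytokines and chemokines were below 0 (median -0.73), 10 of them lower over the list alone. Ccl7 was at -1.74 and Ccl2, which draws monocytes, at -1.54. Ccl7 is a leading gene of cluster 15, whose share of the class was lower with BLM in all 3 targets (62.8% and 50.6% in BLM_Maf against 74.8% and 65.0% in Maf, 16.2% against 37.6% for Apbb2 and 17.7% against 35.6% for Tns3). The dissociation and stress list was below 0 in the same classes, with 21 of 22 members in alveolar and 22 of 22 in interstitial macrophages. In B cells, 19 of 21 type I interferon response genes were below 0 (median -0.34), with Isg15 at -0.98 and Irf7 at -0.62. Proliferation genes were above 0 in alveolar macrophages for 25 of 25 members (median 0.38). Cluster 31, led by the cycling genes Pclaf, Birc5 and Cdk1, held 4.96% and 2.09% of these cells in BLM_Maf against 1.00% and 3.15% in Maf, 7.44% against 2.51% for Apbb2 and 10.8% against 9.73% for Tns3. By fry, 0 of 78 class and list pairs passed: the alveolar macrophage cytokines came nearest (adjusted p = 0.0956). Unadjusted, 3 pairs had a p under 0.05, and camera with an estimated correlation called 0 (smallest adjusted p = 0.109).

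BLM_Maf and Maf were the only contrasted groups with 2 libraries on both sides. In monocytes, Lef1 and Il7r fell in BLM_Maf. Lef1, a transcription factor of T cells, stood at 4.90 and 15.2 CPM in BLM_Maf against 69.9 and 92.2 in Maf (log2 fold change -3.15, SE 0.470, adjusted p = 0.0177). Il7r, the interleukin-7 receptor, stood at 12.2 and 27.6 against 95.3 and 154 (-2.77, SE 0.397, adjusted p = 0.0177). S100a8, a calprotectin subunit and neutrophil marker, fell there too, at 51.4 and 23.5 against 121 and 597 CPM (-3.32, SE 0.545, adjusted p = 0.0221). Barcodes of 100 or fewer UMIs held 381 and 542 CPM of S100a8 in BLM_Maf against 2178 and 2015 in Maf, and neutrophils made up 6.81% and 5.40% of cells against 12.2% and 12.7%. Papss2, which makes the sulfate donor PAPS, rose to 124 and 133 CPM from 23.3 and 27.7 (2.18, SE 0.336, adjusted p = 0.0177). The T cell markers Trbc2, Cd3d and Cd3e had a median log2 fold change of -2.52 in monocytes and did not pass (adjusted p = 0.122 to 0.244).

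In B cells Chil3, an alveolar macrophage marker, rose to 194 and 153 CPM from 40.6 and 53.6 (log2 fold change 1.74, SE 0.211, adjusted p = 0.0347), while barcodes of 100 or fewer UMIs held 4152 and 1397 CPM of Chil3 in BLM_Maf against 739 and 619 in Maf. In interstitial macrophages Mucl1 fell to 1.22 and 0.579 CPM from 160 and 32.8 (adjusted p = 0.0127). In T cells Sorcs1, named after its values were seen, rose to 9.18 and 7.64 CPM from 0.0499 and 0.159 (adjusted p = 0.0206). In all, 3 genes rose and 12 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11 of them in monocytes, among 96621 class and gene pairs of which 12787 had an unadjusted p under 0.05. This balance did not hold throughout: with classes called per cell 9 rose and 6 fell, and without BLM_Maf 1 more rose than fell. The count was 75 without BLM_Maf 1, where Mucl1 was lost (adjusted p = 0.0784), 4400 without BLM_Maf 2, 300 without Maf 1, 3652 without Maf 2, 671 with a block by replicate number and 1488 by DESeq2. Leaving out a library left 1 in its group and 1 residual degree of freedom, so those counts do not measure the effect of that library. With classes called per cell, Lef1 was at -0.16 (adjusted p = 0.870), and Il7r (0.431), Papss2 (0.215), Chil3 (0.141) and S100a8 (0.0706) did not pass either, nor did S100a8 by DESeq2 (0.281) or Lef1 with doublets kept (0.263).

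Among the fixed lists, cytokines were mostly lower in macrophages of BLM_Maf than of Maf, 4 libraries that also enter the comparison across targets. In interstitial macrophages, 22 of 25 were below 0 (median -1.15) and 16 were lower over the list alone, with Ccl2 at -2.45, Ccl12 at -2.23, Ccl7 at -2.35 and Ccl3 at -1.97. In alveolar macrophages 22 of 24 were below 0 (median -0.49) and 8 were lower over the list alone. Fibrosis-associated macrophage genes were above 0 for 20 of 23 members in interstitial macrophages (median 0.61, 1 over the list alone), with arginase, Arg1, at 3.41 and the collagen-degrading protease Ctsk at 1.64. Ccl7 and Ccl12 lead cluster 15, which held 62.8% and 50.6% of the class in BLM_Maf and 74.8% and 65.0% in Maf, and Mmp12, Gpnmb and Trem2 lead cluster 12, which held 37.2% and 49.4% against 25.2% and 35.0%. Type I interferon genes were below 0 for 19 of 22 members in neutrophils (median -0.74, 9 over the list alone) and 20 of 22 in fibroblasts (median -0.67, 5 over the list alone). Of neutrophils, cluster 7 held 75.7% and 70.3% in BLM_Maf against 44.1% and 92.3% in Maf. Cluster 1 held 21.6% and 20.1% of them against 42.5% and 2.36%. Fibroblasts had 19 of 22 proliferation genes above 0 (median 1.45, 11 over the list alone), with Top2a at 3.13 and Cenpf at 4.05, and 20 of 30 extracellular matrix genes above 0 (median 0.34), with elastin, Eln, at 1.53. Cluster 5 held 23.1% and 52.3% of fibroblasts in BLM_Maf against 53.7% and 59.1% in Maf, and cluster 10 held 74.0% and 43.4% against 39.6% and 38.4%. In B cells 12 of 13 class II presentation genes were below 0 (median -0.61, 5 over the list alone), with H2-DMa at -0.86, and in T cells 11 of 25 effector and checkpoint genes were above 0 (median -0.10).

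Over all genes tested, 0 members of these lists passed in these classes, and 0 of 82 class and list pairs passed by fry (smallest adjusted p = 0.529; 4 had an unadjusted p under 0.05) or by camera with an estimated correlation (0.527). With a block by replicate number 0 passed too (smallest fry adjusted p = 0.292).

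BLM_Maf against model compared lungs of the Maf title with the single lung titled model. Ifi27l2a, Slfn5 and Lrg1 fell in neutrophils of BLM_Maf. Ifi27l2a, induced by interferon, stood at 122 and 215 CPM against 940 (log2 fold change -2.66, SE 0.346, adjusted p = 6.88e-04). Slfn5, also interferon-induced, stood at 16.1 and 29.3 against 86.7 (-2.08, SE 0.381, adjusted p = 0.0279), and Lrg1, a granule glycoprotein, at 177 and 174 against 598 (-1.96, SE 0.341, adjusted p = 0.0167). Chil3 rose in B cells, to 194 and 153 CPM from 26.2 (2.60, SE 0.285, adjusted p = 0.00274), and barcodes of 100 or fewer UMIs held 578 CPM of it in model against 4152 and 1397 in BLM_Maf.

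The type I interferon list had a median below 0 in all 7 classes where it was measured. All 23 measured members were below 0 in alveolar macrophages (median -1.38, 12 lower over the list alone), with Rtp4 at -2.35, Oas3 at -2.27 and Bst2, which tethers enveloped viruses, at -0.90. In dendritic cells 22 of 23 were below 0 (median -1.15, 8 over the list alone), in neutrophils 18 of 23 (median -0.96, 10 over the list alone and 1, Ifi27l2a, over all genes), and in interstitial macrophages 22 of 24 (median -0.92, 7 over the list alone). The medians were -0.85 in T cells, -0.56 in B cells and -0.30 in monocytes. Class II presentation genes were below 0 for 12 of 13 members in alveolar macrophages (median -0.90, 6 over the list alone), with H2-Eb1 at -1.47, H2-Aa at -1.37 and the invariant chain Cd74 at -1.41. In monocytes 8 of 10 were below 0 (median -1.32, 6 over the list alone). Lipid-handling genes were above 0 for 12 of 18 members in alveolar macrophages (median 0.39, 4 over the list alone), with the scavenger receptors Cd36 at 1.87 and Marco at 1.63. Cluster 17 held 12.3% and 24.3% of these cells in BLM_Maf and 1.46% in model.

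In this comparison 2 genes rose and 7 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 6201 of 98970 class and gene pairs had an unadjusted p under 0.05. The balance was the reverse without BLM_Maf 1 and by DESeq2, where more genes rose than fell. Of 78 class and list pairs 0 passed by fry (smallest adjusted p = 0.484; 6 had an unadjusted p under 0.05) or camera (0.744). DESeq2 called 71, and the count was 33 without BLM_Maf 1, where Ifi27l2a, Slfn5 and Lrg1 were lost (adjusted p = 0.821 each), and 932 without BLM_Maf 2. Slfn5 and Lrg1 were also lost with doublets kept (0.136 and 0.148), and with classes called per cell so were Slfn5 (0.359), Lrg1 (0.223) and Chil3 (0.759). The fits without a BLM_Maf library had 1 residual degree of freedom, so their counts do not measure the effect of that library.

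Maf against PBS compared animals of the Maf title without BLM with the single PBS lung. Genes of the fibrosis-associated list rose in macrophages of Maf. In interstitial macrophages osteopontin, Spp1, rose from 9.11 CPM to 3142 and 14339 (log2 fold change 10.16, SE 1.74, adjusted p = 0.00680). Lipoprotein lipase, Lpl, rose 39.1-fold (counting interval 23.7 to 69.9, adjusted p = 0.00678), the protease Ctsk 66.3-fold (25.8 to 243, adjusted p = 0.00464) and Gpnmb, a lysosomal membrane glycoprotein, 355-fold (63.7 to 14040, 1 UMI in PBS, adjusted p = 0.00160). Rnf217, a ubiquitin ligase, rose 53.4-fold (9.54 to 2112, 1 UMI in PBS, adjusted p = 7.12e-04). Cd163, the haemoglobin scavenger receptor, fell from 444 to 52.0 and 61.0 CPM (log2 fold change -2.66, SE 0.325, adjusted p = 7.12e-04), and Plac8, a classical monocyte marker, from 78.3 to 5.47 and 4.38 CPM (-3.72, SE 0.435, adjusted p = 7.12e-04).

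Of the fibrosis-associated macrophage genes, 20 of 24 were above 0 in interstitial macrophages (median 2.22, or 2.05 with the member at 0 in PBS set to its bound), 15 of them over the list alone and 8 over all genes. In alveolar macrophages 21 of 23 were above 0 (median 1.44), 16 over the list alone and 2 over all genes. These were the growth factor Igf1 (2.90, SE 0.284, adjusted p = 0.0446) and the tetraspanin Cd63 (2.43, adjusted p = 0.0482), with the lipid receptor Trem2 at 2.78. Neither Igf1 nor Cd63 was among the 13 calls within cluster 17. That cluster held 72.6% of alveolar macrophages in PBS against 43.0% and 20.9% in Maf, cluster 9 held 0.595% against 32.4% and 36.1%, and cluster 19 held 3.87% against 17.9% and 29.8%. All 25 proliferation genes were below 0 in alveolar macrophages (median -1.78, 19 over the list alone), with Cdk1 at -1.85, and cluster 31, led by Pclaf, Birc5 and Cdk1, held 6.25% of the class in PBS against 1.00% and 3.15% in Maf. In T cells 18 of 25 effector and checkpoint genes were above 0 (median 1.01, 9 over the list alone), with Havcr2 at 2.66, Pdcd1 at 1.69 and Tnfrsf9 at 1.97. Cluster 11, led by Foxp3, Ctla4 and Tnfrsf9, held 2.60% of T cells in PBS against 6.51% and 7.99% in Maf, cluster 3, led by Icos and Cd40lg, 7.14% against 18.4% and 32.0%, and cluster 2, led by Lef1 and Tcf7, 38.8% against 26.5% and 18.9%. Surfactant and secretory transcripts were below 0 for 10 of 10 members in alveolar macrophages (median -2.91, 5 over the list alone and 2 over all genes). The club cell transcript Scgb1a1 fell in monocytes (-4.16, adjusted p = 0.00173), where barcodes of 100 or fewer UMIs held 29373 CPM of it in PBS and 1591 and 2263 in Maf.

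These are among 131 genes that rose and 46 that fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 129 in interstitial macrophages, 34 in alveolar macrophages and 7 each in monocytes and neutrophils, and all rest on 1 PBS library with 86 interstitial and 336 alveolar macrophages. By fry 0 of 78 class and list pairs passed (smallest adjusted p = 0.188; 5 had an unadjusted p under 0.05), as by camera (0.358). The count was 2759 without Maf 1, 1328 without Maf 2, 96 with only the 6 libraries of the same set and 588 by DESeq2. The fits without a Maf library had 1 residual degree of freedom, so their counts do not measure the effect of that library. Plac8 was at 0.91 (adjusted p = 0.650) with classes called per cell, and within cluster 15, which held most PBS cells of the class, Plac8 was at -3.57 (SE 0.461, adjusted p = 4.72e-04) and Cd163 at -1.85 (SE 0.357, adjusted p = 0.0361). Spp1, Lpl, Ctsk, Gpnmb and Rnf217 were not called within cluster 15, and cluster 12, led by Mmp12 and Gpnmb, held 1 PBS cell. Of the 129 calls of the class, 65 kept at least 50% of their log2 fold change within cluster 15. A lost call in this smaller fit therefore does not by itself show a cluster shift.

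The difference of differences asked whether BLM_Maf differed from Maf as model differed from PBS. The model and PBS lungs lay far apart in interstitial macrophages, and the BLM_Maf and Maf lungs less so. Rnf217 stood at 76.0 CPM in model against 1.82 in PBS, and at 93.2 and 89.0 in BLM_Maf against 76.1 and 108 in Maf (adjusted p = 0.0119). Spp1 stood at 18980 against 9.11 CPM, and at 10013 and 23927 against 3142 and 14339 (log2 difference -10.40, adjusted p = 0.0274). In neutrophils the acute-phase gene Saa3 stood at 22.1 CPM in model and 4.07 in PBS, and at 0 and 2.32 in BLM_Maf against 9.81 and 9.61 in Maf (adjusted p = 0.0145). Scgb1a1 in neutrophils stood at 36.5 against 849 CPM, and at 54.6 and 157 against 152 and 170 (log2 difference 3.74, SE 0.614, adjusted p = 0.0145). Its level in barcodes of 100 or fewer UMIs was 1273 CPM in model and 29373 CPM in PBS.

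Of 60 calls by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 16 were higher and 44 lower, 46 of them in interstitial macrophages. The same PBS library enters this and the comparison before it, so they are not independent. A fit without 1 of the Maf or BLM_Maf libraries had 1 residual degree of freedom, so its count does not measure the effect of that library. The count was 152 without BLM_Maf 1, 2088 without BLM_Maf 2, 1815 without Maf 1 and 1671 without Maf 2, 31 with DESeq2's size factors, 15 with only the 6 libraries of the same set and 329 by DESeq2. Saa3 and Scgb1a1 were lost without BLM_Maf 1 (adjusted p = 0.836 and 0.158), by DESeq2 (0.167 and 1), with doublets kept (0.128 each) and with classes called per cell (0.123 each).

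Model against PBS set single libraries side by side, with counting intervals and no test between animals. Alveolar macrophages of model had 11401 CPM of Spp1 against 268 in PBS, a ratio of 42.5 (39.8 to 45.4), and 19.2 times (15.9 to 23.3) the apolipoprotein Apoe. The junction gene Patj had a ratio of 0.0211 (0.0146 to 0.0297), and the keratin Krt79 stood at 8.35 CPM in model and 334 in PBS. Krt79 is a leading gene of cluster 17, which held 72.6% of alveolar macrophages in PBS and 1.46% in model. Interstitial macrophages of model had ratios of 19.5 (14.4 to 27.0) for fibronectin, Fn1, and 15.8 for the fatty acid-binding Fabp5. The proton pump subunit Atp6v0d2, a marker of alveolar macrophages, stood there at 714 CPM against 41.9 in PBS. Ratios were 0.0274 for the B cell chemokine Cxcl13, 0.0175 for the neutrophil marker Mmp9 and 0.0425 for Bmp2. Cluster 12, led by Mmp12 and Gpnmb, held 1.16% of this class in PBS, 1 cell, and 49.1% in model. Cluster 15 held 98.8% and 50.9%. Fibroblasts of model had 281 CPM of Spp1 against 1.52 in PBS, a ratio of 185 (121 to 299), and ratios of 39.4 for Kif26b, 30.6 for Saa3, 0.132 for Nup210l, 0.162 for Gzma and 0.0210 for Scgb1a1. Barcodes of 100 or fewer UMIs held 3960 CPM of Spp1 in model and 64.6 in PBS, and NK cells, which express Gzma, made up 6.02% and 16.5% of cells. Secretory transcripts had a median below 0 in all 10 classes where they were measured, with a median log2 ratio of -1.72 in fibroblasts.

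Each list median named here lay beyond those of all 10000 random lists matched on expression. Random lists draw genes singly within the same 2 libraries. They reflect neither the correlation among members of a list nor the spread between animals, so this rank is not a test of model against PBS. Fibrosis-associated macrophage genes had a median log2 ratio of 1.22 in alveolar (18 of 23 above 0) and 2.51 in interstitial macrophages (20 of 23). Both classes lay largely in different clusters in PBS and model, as given above. Type I interferon genes had medians of 1.45 in alveolar macrophages (23 of 23), 0.71 in fibroblasts (22 of 23) and 3.79 in alveolar type 2 cells (17 of 17; 30 cells in model and 106 in PBS). Alveolar type 2 cells also had higher transitional-state genes (median 2.48, 19 of 20) and lower surfactant and lipid genes (-1.67, 1 of 20 above 0). Cluster 32, which made up this class, also had the alveolar type 1 markers Ager and Cldn18 among its leading genes. Its marker score was 5.36 for alveolar type 2 cells and 7.23 for club or secretory cells. No test set these values apart from a changed mix of cells. In fibroblasts 25 of 30 extracellular matrix genes were above 0 (median 0.75) and 15 of 20 TGF-beta response genes (0.34). Cluster 5 held 69.6% of fibroblasts in PBS and 59.4% in model, and cluster 10 held 20.6% and 36.8%. In T cells effector and checkpoint genes had a median of 1.06 (21 of 25) and naive and memory genes -0.72 (0 of 12 above 0), while macrophage markers in the same T cells had a median of 1.03. Cluster 2, led by Lef1 and Tcf7, held 38.8% of T cells in PBS and 20.2% in model, cluster 3, led by Icos and Cd40lg, 7.14% and 30.2%, and cluster 11, led by Foxp3, Ctla4 and Tnfrsf9, 2.60% and 13.3%. In alveolar macrophages proliferation genes had a median of -1.68 (0 of 25 above 0; the cycling cluster 31 held 6.25% of the class in PBS and 4.16% in model) and lipid-handling genes -0.67 (5 of 18).

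**Figure D2:**
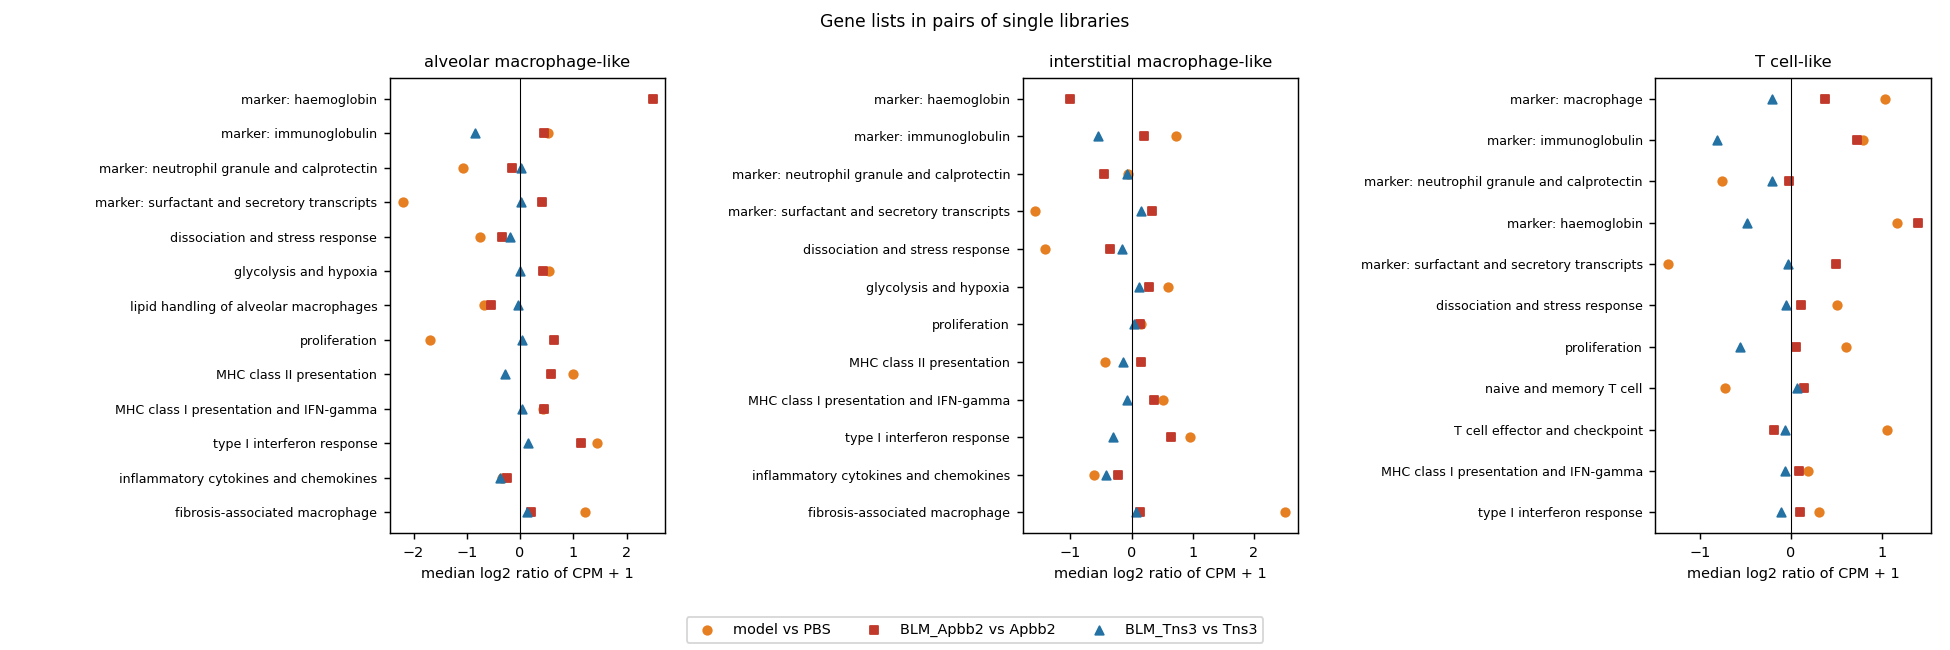
Median log2 ratio of CPM + 1 (horizontal axis) of each gene list (vertical axis) in 3 cell classes, with 1 point per pair of single libraries. Fibrosis-associated macrophage genes lie at 2.51 in interstitial macrophages for model against PBS, and type I interferon genes lie right of 0 in alveolar macrophages at 1.45 for that pair and 1.14 for BLM_Apbb2 against Apbb2.

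BLM_Apbb2 against Apbb2, again single libraries with no test, had higher interferon-induced genes in macrophages. In alveolar macrophages Arg1 had a ratio of 7.39 (6.61 to 8.29) and Ifi27l2a of 5.06 (4.81 to 5.33). The complement subunit C1qa, a marker of interstitial macrophages, had a ratio of 5.02. Patj had a ratio of 0.0391, Htr2c of 0.0805 and the lipid-droplet gene Cidec of 0.0980. The last 2 lead cluster 17, which held 3.94% of these cells in BLM_Apbb2 and 50.0% in Apbb2. Interstitial macrophages had ratios of 3.50 (2.93 to 4.21) for Rsad2, an antiviral enzyme, 3.24 for AW112010, 0.0558 for Cxcl13 and 0.289 for the neutrophil marker S100a9. Scgb1a1 was at 4.02 but at 0.149 with classes called per cell. Type I interferon genes had a median log2 ratio of 1.14 in alveolar (23 of 23 above 0) and 0.65 in interstitial macrophages (22 of 23). Endothelial cells had 20 of 22 proliferation genes above 0 (median 0.71).

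BLM_Tns3 against Tns3, single libraries with no test, had named ratios in alveolar macrophages between 0.468 for the zinc transporter Slc39a12 and 1.76 for the respiratory chain gene Uqcrb. The chaperones Hsph1 and Hspa1b had ratios of 0.489 and 0.494, Uchl3 of 1.71 and Fabp5 of 1.68 (1.66 to 1.71). In interstitial macrophages the scavenger receptor Marco, high in alveolar macrophages, had a ratio of 0.0195 and Retnla of 0.0710. Uqcrb had a ratio of 1.83, the chemokine receptor Ccr2, a marker of classical monocytes, of 1.70 and Rgs1 of 1.68. Saa3 was at 0.128 but at 1.78 with classes called per cell. Fibroblasts, 39 in BLM_Tns3 and 203 in Tns3, had ratios of 0.0700 for Ugdh, which makes hyaluronan precursors, 0.0811 for Fosb and 0.0858 for Tnfaip6. Ppp4r4 had a ratio of 8.02 and Car2 of 5.72. The neutrophil marker S100a9 was at 9.39 but at 0.916 with classes called per cell. Of these fibroblasts, cluster 5 held 25.6% in BLM_Tns3 and 69.5% in Tns3, and cluster 10 held 56.4% and 25.1%. Cytokine lists had medians of -0.38 in alveolar (3 of 25 above 0) and -0.42 in interstitial macrophages (2 of 25), interferon genes of -0.31 in interstitial macrophages (5 of 24) and 0.50 in neutrophils (21 of 23).

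Pairs of the Apbb2 and Tns3 titles with model or PBS crossed the library sets. Spp1 in alveolar macrophages was 28.5 times the PBS level in Apbb2 and 52.4 times in Tns3, Fn1 in interstitial macrophages was 28.0 times the PBS level in Tns3, and Il6 in interstitial macrophages of BLM_Tns3 was 7.48 times the model level. Inhba was 9.11 times and Il23a 30.6 times the model level in alveolar macrophages of BLM_Tns3 and BLM_Apbb2, respectively. In macrophages the lowest ratio of each such pair was that of AY036118, at 0.00138 to 0.00372, a transcript that splits the sets.

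Of the genes in the titles, Apbb2, an adaptor that binds the amyloid precursor protein, rose in Maf against PBS in alveolar macrophages (5.64 CPM in PBS, 44.4 and 80.9 in Maf; log2 fold change 3.65, SE 0.453, adjusted p = 0.0446) and interstitial macrophages (41.9 CPM against 136 and 220; 2.39, SE 0.480, adjusted p = 0.0184). Over all cells Apbb2 stood at 43.0 CPM in PBS, 73.8 in model, 111 and 81.0 in BLM_Maf, 49.0 and 69.7 in Maf, 112 in BLM_Apbb2, 79.3 in Apbb2, 134 in BLM_Tns3 and 144 in Tns3. Maf, a transcription factor of macrophages and T cells, stood at 143 CPM over all cells in PBS, 220 in model, 253 and 145 in BLM_Maf, 203 and 230 in Maf, and 48.5 to 85.1 in the other set. In interstitial macrophages it stood at 894 CPM in PBS, 340 in model and 271 and 321 in Maf (log2 fold change for Maf against PBS -1.28, SE 0.396, adjusted p = 0.144). Tns3, a focal adhesion protein, stood at 60.4 CPM in PBS, 74.1 in model, 121 and 95.8 in BLM_Maf, 77.9 and 81.5 in Maf, 50.7 in BLM_Apbb2, 58.1 in Apbb2, 66.2 in BLM_Tns3 and 79.6 in Tns3. Those were the 2 calls for the 3 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The smallest adjusted p was 0.435 across the BLM titles, 0.223 for BLM_Maf against Maf, 0.305 against model and 0.101 for the difference of differences. DESeq2 called 6. Neither of the 2 Apbb2 calls recurred within 1 cluster. Cluster 17 held 72.6% of alveolar macrophages in PBS against 43.0% and 20.9% in Maf, and cluster 15 held 98.8% of interstitial macrophages against 74.8% and 65.0%. Those fits had fewer cells, so a lost call there does not by itself show a cluster shift. The alveolar macrophage call was lost with only the 6 libraries of the same set (adjusted p = 0.0562), and the interstitial macrophage call with classes called per cell (0.110).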

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

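The count of other splits of the libraries, the test of secretory transcripts, the share of T cell markers other than CD3 and the test within a cluster for the difference of differences were chosen only after their results were seen. The tests within clusters for Maf against PBS and of the median of T cell markers were added once the calls were known, but their bounds were set before the values they measure were seen.

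Macrophages set PBS apart from the Maf libraries, with 129 genes called in interstitial and 34 in alveolar macrophages for Maf against PBS, and the test of whether the change from Maf to BLM_Maf equals that from PBS to model gave 60 calls, 46 of them in interstitial macrophages. A shift in the clusters that make up each class could account for such calls, because cluster 15 held 98.8% of interstitial macrophages in PBS against 74.8% and 65.0% in Maf. Within cluster 17, 26 of the 34 alveolar macrophage calls (76.5%, exact 95% interval 58.8 to 89.3) kept their sign and at least 50% of their log2 fold change. Within cluster 15, 32 of the 46 calls just named did (69.6%, 54.2 to 82.3). Both shares lay above the bound of 50%, so in these libraries most of these fold changes were not lost within 1 cluster. The intervals count genes as independent, although the genes all share 1 PBS library, so they do not extend this to other animals. Within the cluster, 9 of the 34 and 6 of the 46 were still called, and 14 of the 46 had 3 or fewer counts in PBS. Free RNA can also carry a fold change into a cluster, and was not set apart. The secretory transcripts Scgb1a1 and Sftpc were among the calls within cluster 17. Within cluster 15, 65 of the 129 interstitial macrophage calls for Maf against PBS kept sign and size by the same rule (50.4%, 41.5 to 59.3). That share lay close to the bound, so for these a cluster shift and a change within cells cannot be told apart. A difference between the animals of these titles stays open and untested, since PBS was 1 library with 86 interstitial macrophages.

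Scgb1a1 was lower in monocytes, and Scgb1a1 and Scgb3a2 in neutrophils, of Maf than of PBS, classes not known to make them. Free RNA from other cells is a candidate explanation, and Scgb1a1 stood at 29373 CPM in the barcodes of 100 or fewer UMIs in PBS and at 1591 and 2263 CPM in Maf, a log2 ratio of -3.93. Over the classes, its median log2 fold change was -2.61, and every class compared was below 0, from -2.06 in interstitial macrophages to -4.16 in monocytes. Alveolar macrophages (-3.94) and monocytes (-4.16) lay over 1 log2 unit from that median, though by less than their standard errors beyond it. The bound as written counted at least 2 such classes against free RNA as the cause, with no allowance for standard errors. Scgb3a2 lay over 1 log2 unit from its median of -2.64 in alveolar macrophages (-4.44) and NK cells (-4.02), and stood at -2.26 (SE 1.18) in monocytes. Club or secretory cells made up 1.37% of cells in PBS and 0.0347% and 0.113% in Maf. The classes beyond 1 log2 unit all departed toward the log2 ratio in barcodes of 100 or fewer UMIs, -3.93 for Scgb1a1 and -3.84 for Scgb3a2. Meeting the bound therefore does not count against free RNA. The other classes fell by less than that ratio, so the explanation stays open, and no biological explanation was tested.

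T cell transcripts were lower in monocytes of BLM_Maf than of Maf. T cells or their RNA within the monocyte class may account for it: markers outside the called genes had a median log2 fold change of -2.52, with Trbc2 at -3.09, Cd3d at -2.52 and Cd3e at -2.33 (adjusted p 0.122 to 0.244, so none passed). The monocyte class held 8.94% and 20.8% cells with a CD3 UMI in Maf 1 and 2 and 0.606% and 5.88% in BLM_Maf 1 and 2, against 2.59%, 7.58%, 2.01% and 4.61% of B cells in the same order (median UMIs per cell 3474, 5946, 4844 and 4206 in monocytes and 1697, 2808, 2398 and 2228 in B cells). In Maf, those cells held 92.3% and 85.7% of the class's UMIs of the T cell markers other than CD3, against 34.9% and 7.95% in B cells, which is consistent with whole T cells among the monocytes. Whether BLM also changed monocytes in these animals stays open.

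For the 4 libraries with BLM in the title against 4 without, 8 of 34 splits, the real one included, gave at least its 2 calls, so chance cannot be excluded. With the target as a covariate 3 pairs of splits are the same fit, which leaves 31 distinct fits, 7 of them with at least 2 calls. The highest other, 2199, came from 1 such pair, whose fit contrasts only BLM_Maf with Maf, a difference in the labels themselves. Of the remaining 30 fits 6 gave at least 2 calls, and the highest other gave 596. At an unadjusted p under 0.05, 4 of the 34 splits gave at least the 7856 of the real one, and the highest other gave 15576. Most splits were not balanced over the targets. Among balanced ones the most calls were 4, and the real split had the most pairs at an unadjusted p under 0.05, ahead of 6622. Balanced splits are too few to give a share under 0.05.

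In 6 of 44 groups tested 1 library stood far from the others with the same BLM label. The rule flags about 1 in 20 groups of independent values of one kind. These groups mix targets and library sets, and their shares come from the same libraries, so the 6 cannot be set against that rate. Among the libraries with BLM in the title, smooth muscle or pericytes made up 0.783% of cells in BLM_Maf 2, with the nearest other at 0.0134%. Among those without BLM, Tns3 had 0.561% alveolar type 2 cells (nearest 0.0798%), 0.504% ciliated cells (nearest 0.0807%) and 1.85% mesothelial cells (nearest 0.0347%). In that group, Apbb2 had 26.5% neutrophils (nearest 12.7%) and 58.1 CPM of Tns3 over all cells (nearest 77.9 CPM).

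The share of alveolar macrophages was higher with BLM by 4.24 points in the Maf libraries and lower in the others, at -4.29 points for Apbb2 and -5.07 points for Tns3, a difference that was not tested. The share of interstitial macrophages was higher with BLM by 3.70 points in the Maf libraries and stood at -0.282 points for Apbb2 and -3.80 points for Tns3, likewise not tested. Cluster 48, which matched no class and was led by Tpm1, Gng11 and Ctla2a, had a median UMI count 0.187 times that of its libraries and its highest marker scores for platelets or megakaryocytes (3.82) and capillary endothelial cells (3.55). It held 0.519% (0.400 to 0.662) of BLM_Tns3 cells and 0.0173% to 0.268% elsewhere. Its cells followed the library sets, with 64 in BLM_Tns3, 21 in Tns3, 37 in BLM_Apbb2 and 28 in Apbb2, against 2 to 9 in each of the other 6 libraries. Cluster 58 was led by Alox15, Prg4 and Saa3. Its highest marker scores were for interstitial macrophages (2.70) and nonclassical monocytes (0.883). It was left unnamed because 1 endothelial marker and 0 interstitial macrophage markers were among its leading genes. It held 0.665% (0.529 to 0.824) of BLM_Tns3 cells, 0.661% of Tns3 cells, 2 cells in Apbb2 and 0 in the other 7 libraries. There 0 of 7486 cells, the fewest, leaves an exact upper bound of 0.0493%.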

How the results depend on the processing

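The crossed block, the leave-one-out fits of the difference of differences, the single-cluster fits and the alternatives for single-library pairs were chosen only after seeing the data, the single-cluster fits once the calls were known. List tests for Maf against PBS and random lists for single-library pairs were not planned either. Of the alternative values of single genes and shares, 261 kept direction and side of the threshold, 35 lost the call and 9 reversed; of the counts, 46 stayed within 1.5 times and 55 moved. The cause was not tested except where named.

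Calls are given for the BLM titles (2), BLM_Maf against Maf (15), BLM_Maf against model (9), Maf against PBS (177) and the difference of differences (60), in this order. The DESeq2 Wald test gave 181, 1488, 71 (55 higher, 16 lower), 588 and 329. No expression filter gave 1603, 4486, 584, 1564 and 1513, with an infinite prior for the dispersion in 8 of 8 classes of the first, where simulated false calls in T cells were 18% of calls against 6.14% with the filter, and in interstitial macrophages 14.8% against 7.02%. Doublets kept gave 0 (7789 at an unadjusted p under 0.05), 23, 14, 574 and 160. Classes called per cell gave 4 for the first, 3 for the third and 106 (54 higher, 52 lower) for the last. A mitochondrial limit of 10% gave 4 for the first and 24 for the second, and a minimum of 1000 UMIs gave 18 for the third. DESeq2's size factors gave 31 for the last. A fit of 6 libraries gave 96 for Maf against PBS and 15 for the last.

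For the BLM titles, no target covariate gave 0 (4531 at an unadjusted p under 0.05) and the replicate block in its place 10. For BLM_Maf against Maf, the replicate block gave 671, the fit of all 10 libraries 79, and a crossed block, chosen after seeing the data, 1930. Under the crossed block 3 named genes kept their call and 3 lost it. Replicates did not pair by their deviations (median correlation -0.12). Leaving out 1 library gave 3 (without BLM_Maf 1) to 15 (without Tns3) for the BLM titles, 75 (without BLM_Maf 1) to 4400 (without BLM_Maf 2) for BLM_Maf against Maf, 33 (without BLM_Maf 1) to 932 (without BLM_Maf 2) against model, 1328 (without Maf 2) to 2759 (without Maf 1) against PBS and 152 (without BLM_Maf 1) to 2088 (without BLM_Maf 2) for the last. A lone library left in a group was assumed to vary like the others. Except for the BLM titles, these fits had 1 residual degree of freedom. The prior for the dispersion was infinite in 5 of 9 classes for BLM_Maf against Maf without Maf 2. It was infinite in 4 of 8 for Maf against PBS without Maf 2, and in 0 of 9 for BLM_Maf against Maf without BLM_Maf 1. These counts therefore do not measure the effect of 1 library.

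Fits within 1 cluster, with fewer cells, gave 10 interstitial macrophage calls for Maf against PBS, 7 of them among the 129 of the class, and 13 for the difference of differences, 6 of them among the 46. In alveolar macrophages they gave 13, 9 of them among the 34. The 2 calls of title genes became 6 with DESeq2, 11 with no filter and 4 with doublets kept, and of 17 named genes 11 passed with doublets kept and 6 with classes per cell. The alveolar macrophage share difference (-0.220 points) became 0.0464 with classes per cell, 0.0227 with model and PBS added, 1.13 without BLM_Maf 1, 0.697 without BLM_Maf 2, 2.38 without Apbb2 and 2.42 without Tns3, and was lowest at -2.94 without Maf 2. That of interstitial macrophages (0.827) became -0.287 without Maf 1 and -0.0820 without Maf 2, and was highest at 2.70 without Tns3. Plac8 in interstitial macrophages, at -3.72, became 0.91 with classes per cell. No gene list passed fry under any alternative run.

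Simulations covered only T cells and interstitial macrophages: with 86 interstitial macrophages in PBS, changes of 4-fold were recovered in 29% of genes for Maf against PBS and 3% for the difference of differences.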

Other observations

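The genes, classes and lists in this part were chosen only after their values were seen, and are given as values with no further test. In interstitial macrophages, PBS lay below all 9 other libraries in genes called for Maf against PBS. Rnf217 stood at 76.0 to 121 CPM in those 9 libraries, Gpnmb at 248 to 1156 CPM and Spp1 at 3142 to 28465 CPM, against 1.82, 1.82 and 9.11 CPM in PBS. The cluster led by Ccl8, Pf4 and Folr2, genes of resident perivascular macrophages, held 98.8% of this class in PBS, 50.9% in model, 62.8% and 50.6% in BLM_Maf and 74.8% and 65.0% in Maf. It held 16.2% in BLM_Apbb2 and 37.6% in Apbb2, and 17.7% in BLM_Tns3 and 35.6% in Tns3. Most other cells of the class lay in a cluster led by Mmp12, Gpnmb, Mfge8, Apoe and Trem2.

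Epithelial and endothelial cells differed within the single pairs as well. Alveolar type 2 cells of BLM_Tns3 (71 cells) had a median log2 ratio of -2.25 for surfactant and lipid genes against Tns3 (50 cells), with 1 of 20 members above 0. This class also had alveolar type 1 markers among its leading genes, so a changed mix of cells was not set apart. Endothelial cells of BLM_Apbb2 had medians of 0.90 for glycolysis and hypoxia genes, 0.52 for the capillary injury response and -0.38 for class I presentation genes (1 of 27 above 0) against Apbb2. Endothelial cells of model (82 cells) had a median of 1.62 for proliferation genes against PBS (347 cells), with 14 of 16 above 0. The lymphatic cluster 34 held 53.7% of these cells in model and 29.7% in PBS, and the capillary cluster 13 held 25.6% and 48.4%. T cells of BLM_Tns3 had 0 of 25 proliferation genes above 0 against Tns3 (median -0.56), and those of model had 23 of 25 above 0 against PBS (median 0.61). The cycling cluster 27, led by Top2a and Mki67 among others, held 1.20% of T cells in BLM_Tns3 and 2.72% in Tns3, and 3.81% in model and 2.15% in PBS.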
